A study of Mus musculus with 6 samples.

How the data were processed

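RNA of cells in bronchoalveolar lavage fluid of mice was measured by RNA sequencing in 6 libraries, 3 from mice given vehicle (replicates 2, 3 and 4 in the labels) and 3 from mice given 20 µg of sulfatide into the peritoneal cavity (replicates 1, 2 and 3). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The labels also do not say whether the mice had undergone lung ischemia and reperfusion, which the title of the series names.

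Per the labels' protocols, RNA was extracted with TRIzol, mRNA was enriched by poly(A) selection, and strand-specific (dUTP) libraries were sequenced as paired-end reads on an Illumina platform. The genome build was mm10, per the submitters' processing notes. The aligner, the program that counted fragments and the gene annotation are not given in the sources used here, nor is whether counting used the strand. The authors deposited 1 table of FPKM values (fragment numbers scaled to transcript length and to the total of each library), rounded to 2 decimals, for 22800 gene symbols. The table held 3 further value columns that matched no sample of the series, and these were not used in any step. FPKM are not counts, so a model on a log scale was used and no count model. Rounding and the missing counts leave the absolute depth unknown. The depth of each library relative to vehicle replicate 2 was estimated from the most frequent ratio of their FPKM. Genes at 0.1 to 1.5 FPKM in both libraries were used. The density of ratios at that peak was only 3.01 to 4.14 times its median, so these depths are approximate.

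Values were analysed as log2(FPKM + 1), with no further scaling, for the 10405 genes that reached 1 FPKM in at least 3 libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), in 2-sided tests with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. Log2 fold changes are sulfatide minus vehicle on the log2(FPKM + 1) scale, which understates the change of genes with low values, and are given with their standard error. Folds are ratios of group mean FPKM. An exact permutation test of 3 against 3 libraries cannot give a 2-sided p below 0.1, so none was used for single genes.

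Before the data were examined, 38 gene lists were fixed for cell types that lavage fluid can hold, for macrophage and immune processes, and for RNA quality. Mitochondrially encoded genes were matched under the names the table gives them (ND1 for mt-Nd1, for example). Lists with at least 3 tested members were set against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists tested. The list of sex-linked genes was not tested. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were alternatives. For each list the number of called members is given after adjustment over all genes and after adjustment over the list alone. On data simulated from these libraries (10405 genes, 10 draws with 200 changed genes each), the comparison of vehicle and sulfatide recovered 84.8% of genes changed 2-fold and 46.2% of genes changed 1.5-fold, with 4.59% of calls false. It called 10 of 10 shifted lists and 0 of 350 unshifted lists. The simulated genes were independent of each other, whereas the correlation estimated within the real lists reached 0.855 (cell cycle). The simulation therefore does not give the rate of false list calls in these libraries. It also changed fewer genes (200) than were called in these libraries (1943). Its recovery and share of false calls therefore hold for its own setting only. Camera called 5 to 16 lists in divisions of the libraries that mixed the groups. Part of the group difference remains in such divisions, so these counts are not a rate of false list calls.

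The genes named were chosen by a rule fixed before the data were examined. They were the 12 genes with the largest log2 fold change in each direction among those called, with groups that did not overlap, a mean of at least 5 FPKM in the higher group and an official symbol. To these were added up to 4 members with the smallest p of each list described, and a fixed set reported whatever its result (Siglecf, Pparg, Marco, Cd1d1, Cd36, Mrc1, Arg1, Il10, Tgfb1, Tnf, Il1b, Il6, Nos2, Ifng, Cxcl9, Cxcl10 and Ido1). The genes with the highest mean level, Adgre1, Cd68, Saa3 and list members given only by their level (Car4, Fabp1, Krt79, Pf4, Col1a1, Acta2, Hopx, Ly6g, Cxcr2, S100a9, Retnlg, Cd3e, Trac, Sftpc, Il4, Il13 and Il17a) lie outside the rule and were chosen after their values were seen, as were the genes named in the first 2 paragraphs of the other observations.

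The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, robust eBayes, eBayes without a trend, array weights, the replicate number as a block, and each library left out in turn. Leaving out Saa3 with rescaling of each library, and removing from each library a loess trend (span 0.3) on transcript length and GC content, were added after the data were seen. Gene positions, transcript lengths and GC content came from the GENCODE annotation of the mouse build GRCm38, which has the coordinates of mm10. 99.3% of the tested genes had a length and a GC value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.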

Results

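Bronchoalveolar lavage fluid is the saline wash of the airways and alveoli, and its cells are mostly macrophages in healthy mice. Transcript levels were measured in such cells from mice given vehicle (n = 3) or sulfatide (n = 3). Sulfatide is a sulfated glycolipid of myelin that CD1d molecules present to type II natural killer T (NKT) cells. The title of the series places the comparison in a study of how sulfatide-reactive NKT cells act on alveolar macrophages in lung injury. FPKM summed to between 1126779 and 1168474 in the vehicle libraries and to between 1217971 and 1249691 in the sulfatide libraries. In each library 10254 to 10350 genes reached 1 FPKM. Relative to vehicle replicate 2, depth was 1.06 and 1.01 in vehicle replicates 3 and 4, and 1.07, 1.20 and 0.850 in sulfatide replicates 1, 2 and 3. Pearson correlations of log2 values over genes were 0.990 to 0.995 between libraries of a group and 0.967 to 0.982 between groups.

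Macrophage transcripts were abundant in the libraries. Saa3, Fth1, Tmsb4x, Lyz2 and Apoe had the highest mean FPKM. The macrophage genes Adgre1 (532 ± 39.3 FPKM in vehicle and 433 ± 61.8 in sulfatide, SD, n = 3 each) and Cd68 (628 ± 27.7 and 658 ± 46.3) were present in each library. Several genes typical of resident alveolar macrophages were near the floor in both groups. Siglecf was at 0.157 ± 0.0929 FPKM in vehicle and 0.790 ± 0.115 in sulfatide, below the level required for testing. Car4 did not exceed 0.910 FPKM in any library, and Fabp1 and Krt79 were listed at 0 in all 6. Pparg, the regulator of alveolar macrophage development, was at 1.03 ± 0.135 and 0.893 ± 0.341 FPKM (log2 fold change -0.12 ± 0.16, adjusted p = 0.655). The labels name lavage fluid and no cell type, so which macrophages the libraries hold is left open.

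Sulfatide libraries had lower levels of the interferon response and inflammatory cytokine lists than vehicle libraries (adjusted p = 0.255 for each with an estimated correlation). Ranked by log2 fold change on the log2(FPKM + 1) scale, among called genes without overlap of the groups and with a mean of at least 5 FPKM in the higher group, the largest falls were of the cytokine Il6 (49.96 ± 31.5 to 0.517 ± 0.146 FPKM, 96.7-fold lower) and of the chemokines Cxcl10 (1514 ± 628 to 78.8 ± 4.26 FPKM, 19.2-fold lower) and Ccl22 (60.3 ± 15.9 to 2.66 ± 0.543 FPKM, 22.6-fold lower). In the same ranking the largest rise was of Saa1 (2.21 ± 0.923 to 64.8 ± 5.35 FPKM, 29.4-fold higher). Of 10405 genes tested, 865 were higher and 1078 lower in sulfatide by limma, 18.7% in all, and 90 and 295 of these differed at least 2-fold. Of the called genes 44.5% were higher, and 23.6% after rescaling to TPM. The number of higher genes was 268 without vehicle replicate 2, 1421 without vehicle replicate 3, 432 without vehicle replicate 4, 354 without sulfatide replicate 1 and 450 without sulfatide replicate 3, and that of lower genes was 642 without vehicle replicate 2 and 682 without sulfatide replicate 3.

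**Figure D1:**
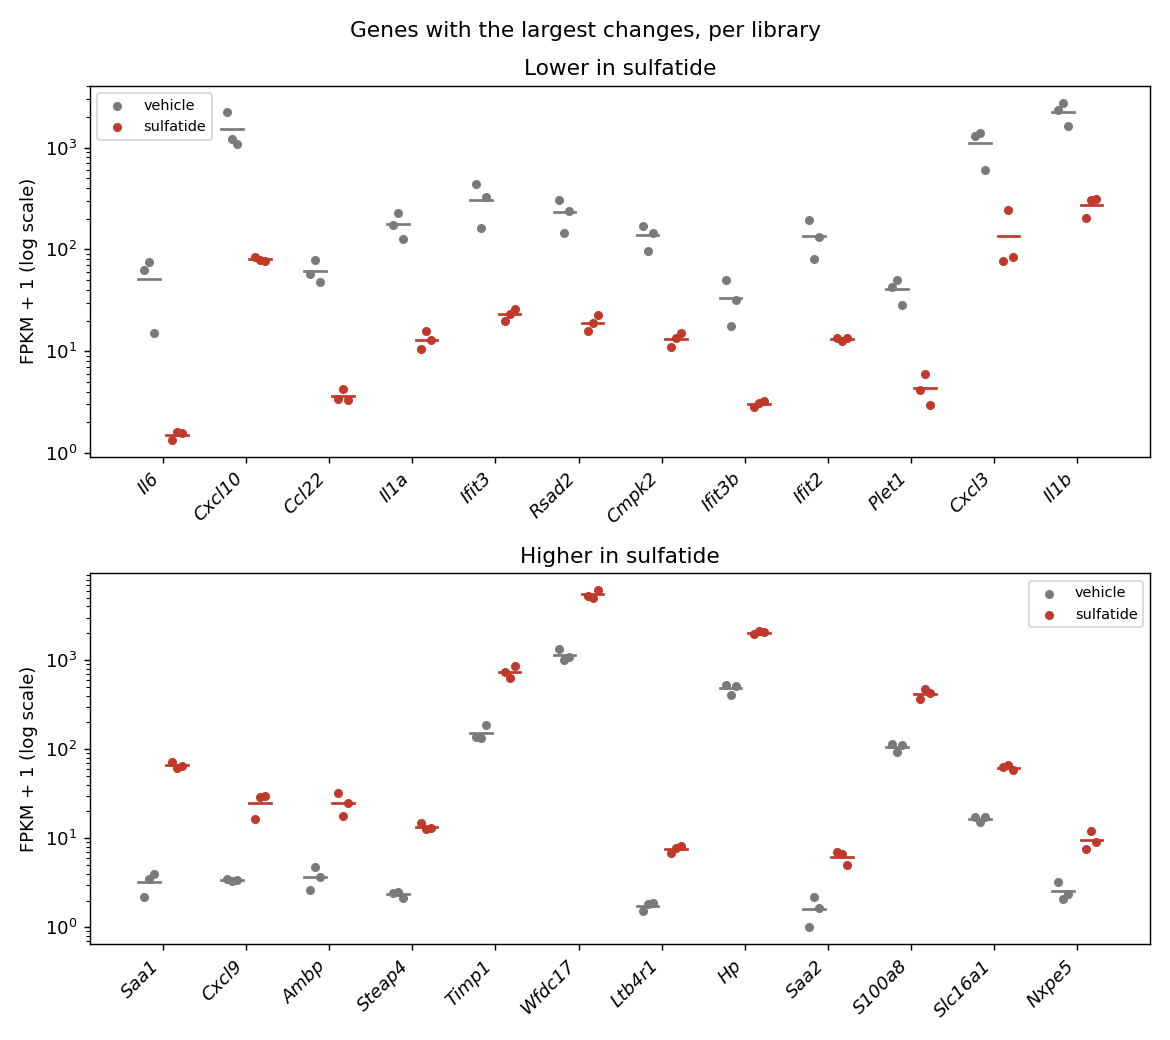
FPKM + 1 on a log axis for the 12 genes with the largest fall (top) and the 12 with the largest rise (bottom) in sulfatide by log2 fold change on the log2(FPKM + 1) scale, with 1 point per library (grey vehicle, red sulfatide, n = 3 each) and a line at the group mean. The groups did not overlap for any of these genes, a condition of their choice, and Il6 was lower in vehicle replicate 4 (14.2 FPKM) than in the other vehicle libraries (62.2 and 73.5 FPKM).

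The type I interferon response list, of genes induced by interferon alpha and beta, fell as a whole. All 30 tested members were lower, also when adjusted over the list alone, with a median log2 fold change of -1.88 (camera adjusted p = 9.41e-32, adjusted p = 0.255 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, fell 12.7-fold (230 ± 80.7 to 18.0 ± 3.53 FPKM), and its neighbour Cmpk2 fell 11.2-fold (136 ± 37.2 to 12.2 ± 2.05 FPKM). Ifit3 (log2 fold change -3.63 ± 0.30, adjusted p = 0.000108) and Ifit2 (-3.26 ± 0.26, adjusted p = 9.21e-05) fell too, as did Usp18, Oas3 and Ifit3b, of which Ifit3b shares much sequence with Ifit3, so that the split of fragments between them is uncertain. Mean levels of the list were 7.74, 7.02 and 7.54 in the vehicle libraries (log2 scale, replicates 2, 3 and 4) and 5.26 to 5.53 in the sulfatide libraries. Of the 25 tested members of the interferon gamma response list, 22 fell and 2 rose, with the same counts adjusted over the list alone (median -1.40, camera adjusted p = 8.06e-16, adjusted p = 0.255 with an estimated correlation). The guanylate-binding proteins Gbp5 (-2.62 ± 0.17, adjusted p = 4.12e-05) and Gbp3 (-2.05 ± 0.15, adjusted p = 7.69e-05) and the cytokine signalling inhibitor Socs1 (-1.67 ± 0.12, adjusted p = 5.85e-05) fell. Cxcl9 rose 9.90-fold (2.42 ± 0.0721 to 24.0 ± 7.55 FPKM), opposite in direction to Cxcl10. The genes lie near each other on chromosome 5, Cxcl9 at 92321347 to 92328079 and Cxcl10 at 92346638 to 92348889. Ifng was listed at 0 in all 6 libraries, and Ido1 did not exceed 0.25 FPKM.

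Inflammatory cytokines and M1-associated genes, those of classically activated macrophages, fell (14 of 21 tested members lower and 2 higher, 16 and 2 adjusted over the list alone, median -0.67, camera adjusted p = 2.18e-08, adjusted p = 0.255 with an estimated correlation). Il1b fell 8.26-fold (2253 ± 566 to 273 ± 61.4 FPKM), Il1a 14.6-fold (175 ± 52.3 to 12.0 ± 2.67 FPKM) and Tnf 5.21-fold (337 ± 97.9 to 64.8 ± 8.16 FPKM). Acod1, which makes itaconate, fell 2.41-fold. Nos2, which encodes inducible nitric oxide synthase, was at 53.8 ± 16.9 FPKM in vehicle and 53.0 ± 6.82 in sulfatide (log2 fold change 0.01 ± 0.20, adjusted p = 0.969). Among chemokines, 12 of 21 tested members fell and 2 rose, 14 and 3 adjusted over the list alone (median -1.09, camera adjusted p = 9.82e-07, adjusted p = 0.309 with an estimated correlation). The median was -0.658 with no filter on low values. Beside Cxcl10 and Ccl22, the neutrophil attractants Cxcl2 (6.65-fold lower) and Cxcl3 (8.13-fold lower) were among those that fell. Cxcl3 was at 1097 ± 435 and 135 ± 94.9 FPKM, a 13.7-fold difference without sulfatide replicate 2. The list of NF-kappaB targets and regulators had 19 of 24 members lower and none higher, 20 adjusted over the list alone (median -0.89, camera adjusted p = 8.06e-16, adjusted p = 0.247 with an estimated correlation), among them Traf1 (4.07-fold lower), Tnfaip2, Nfkb1 and Tnfaip3. Of the inflammasome and pyroptosis list, 9 of 19 members fell and 2 rose, 11 and 3 adjusted over the list alone (median -0.36, camera adjusted p = 0.005, adjusted p = 0.385 with an estimated correlation). These included Il18 (3.79-fold lower), the sensor Nlrp3 (2.48-fold lower) and Mefv (2.11-fold lower). Immediate early and heat shock genes were lower for 13 of 23 members and higher for none, 15 adjusted over the list alone (median -0.43, camera adjusted p = 4.63e-09, adjusted p = 0.247 with an estimated correlation). The near-identical heat shock genes Hspa1a and Hspa1b fell 6.42-fold and 9.76-fold, and the division of fragments between them is uncertain.

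Of the alternative activation and M2-associated list, 4 of 19 tested members rose and 7 fell, 5 and 8 adjusted over the list alone (median -0.05, and -0.151 to 0.0283 over the alternatives, camera adjusted p = 0.225). Mrc1, the mannose receptor (11.1 ± 3.09 to 29.7 ± 4.03 FPKM, adjusted p = 0.00143), Arg1, which encodes arginase (11.6 ± 3.98 to 31.5 ± 11.9 FPKM, adjusted p = 0.0149), and the interleukin receptor chain Il4ra (82.5 ± 14.8 to 176 ± 14.6 FPKM, adjusted p = 0.000711) rose. Il10, an anti-inflammatory cytokine, fell 3.28-fold (12.1 ± 3.69 to 3.68 ± 1.20 FPKM, adjusted p = 0.00397), and Ccl17 fell from 8.58 ± 5.14 to 0.227 ± 0.235 FPKM (37.9-fold, and 81.7-fold without sulfatide replicate 1). Tgfb1 was at 256 ± 3.84 and 256 ± 10.5 FPKM (log2 fold change -0.00 ± 0.07, adjusted p = 0.992). The list of NKT and helper T cell cytokines and receptors had 8 tested members, 2 higher and 3 lower, 2 and 5 adjusted over the list alone (median -0.24, and -0.349 to -0.0996 over the alternatives, camera adjusted p = 0.0709, 0.0215 by fry, and 0.0278 without vehicle replicate 3 and 0.0418 without sulfatide replicate 3). Il4, Il13 and Il17a were listed at 0 in all 6 libraries. Of the CD1 and lipid antigen handling list, 1 of 15 members rose (Ctsl) and 1 fell (Npc2), with the same counts adjusted over the list alone (camera adjusted p = 0.998). Cd1d1, which presents lipids to NKT cells, was at 5.66 ± 0.678 FPKM in vehicle and 3.99 ± 1.12 in sulfatide (log2 fold change -0.44 ± 0.17, adjusted p = 0.102, and 0.0235 without sulfatide replicate 2). Ctsl did not pass without sulfatide replicate 2 (0.0542) or 3 (0.0789).

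Further genes were among the 12 with the largest rises in the ranking above. Haptoglobin (Hp, 483 ± 66.1 to 2040 ± 83.5 FPKM, 4.23-fold), Ambp (8.86-fold), Saa2 (8.52-fold) and S100a8 (105 ± 11.7 to 419 ± 55.3 FPKM, 3.99-fold) rose. Saa2 was at 0.613 ± 0.605 FPKM in vehicle, with 0 in replicate 2, and 5.23 ± 1.06 in sulfatide. Its fold was 16.6 without vehicle replicate 3 and 5.68 without vehicle replicate 2. Saa1 (chromosome 7, 46740497 to 46742980) and Saa2 (46751790 to 46754313) are near-identical neighbours, so the split of fragments between them is uncertain. Saa3, named here after its values were seen, was the gene with the highest mean FPKM and rose from 28515 ± 717 to 82913 ± 3317 FPKM, from 2.40 to 2.58% of the summed FPKM in vehicle libraries to 6.52 to 6.93% in sulfatide libraries. Timp1, an inhibitor of matrix metalloproteinases, rose 4.87-fold (153 ± 29.7 to 743 ± 109 FPKM), and Wfdc17 rose 4.80-fold (1135 ± 166 to 5455 ± 556 FPKM). The iron and copper reductase Steap4 (9.33-fold), the leukotriene receptor Ltb4r1 (8.83-fold), the lactate transporter Slc16a1 (3.94-fold) and Nxpe5 (5.53-fold) completed the 12 genes.

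Cell type lists gave mixed results. The alveolar macrophage identity list was called lower (6 of 17 tested members lower and 2 higher, 7 and 2 adjusted over the list alone, median -0.13, camera adjusted p = 0.00953, adjusted p = 0.361 with an estimated correlation, and 0.0786 with no filter on low values). Its median was -0.303 without vehicle replicate 4, -0.386 without sulfatide replicate 2 and -0.202 without sulfatide replicate 3. It was -0.248 with a pseudocount of 0.1, -0.337 with the filter at 5 FPKM, -0.297 after rescaling to TPM, -0.338 with array weights, -0.277 with the replicate number as a block and -0.246 after removal of a trend on length and GC content. Rescaling to TPM also lowered the median of all tested genes, from 0.0366 to -0.0627. Plet1 fell 11.7-fold, Il18, which is also an inflammasome product, 3.79-fold, the lipoprotein lipase gene Lpl 2.64-fold and Olr1 4.37-fold, while Mrc1 rose. Marco, a scavenger receptor, was at 93.1 ± 11.5 FPKM in vehicle and 103 ± 68.7 in sulfatide (adjusted p = 0.963, and 0.0263 and lower without sulfatide replicate 2, which was at 183 FPKM). Cd36 was at 309 ± 44.6 and 256 ± 58.2 FPKM (adjusted p = 0.246). The dendritic cell list was called lower (5 of 8 members lower and 1 higher, also adjusted over the list alone, median -0.60, camera adjusted p = 0.0161, adjusted p = 0.255 with an estimated correlation, and 0.0614 with no filter on low values). Its median was -0.0523 with no filter and -0.940 with the filter at 5 FPKM. Of its members that fell, Ccl22 is also a macrophage chemokine and Bst2 is induced by interferon. Cd209a was listed at 0 in the vehicle libraries and at 1.19 to 2.59 FPKM in the sulfatide libraries. Of 21 tested monocyte and monocyte-derived macrophage genes, 6 fell and none rose, 6 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.0536, 0.0195 after quantile normalization, 0.0315 with array weights, 0.0299 after removal of a trend on length and GC content, 0.00153 without vehicle replicate 3 and 0.0113 without sulfatide replicate 3). Their median was -0.0993, -0.337 and -0.117 without vehicle replicates 2, 3 and 4 in turn, and -0.0206 with the replicate number as a block. Of 24 neutrophil genes 15 were tested and 6 rose, among them S100a8 and Lcn2, and 1 (Hdc) fell, 6 and 3 adjusted over the list alone (median 0.33, camera adjusted p = 0.222, 0.0485 after rescaling to TPM, 0.0126 with the replicate number as a block, 0.0266 without vehicle replicate 2 and 0.0184 without sulfatide replicate 1). The neutrophil median was 0.171 without vehicle replicate 3, 0.192 without vehicle replicate 4 and 0.0171 with no filter on low values. The neutrophil genes Ly6g and Cxcr2 did not exceed 0.180 FPKM in any library.

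Levels of genes typical of other cells differed widely. The platelet gene Pf4, which macrophages can also express, was at 854 ± 308 FPKM in vehicle and 859 ± 160 in sulfatide, and Col1a1 (19.7 ± 4.10 and 14.8 ± 2.43 FPKM), Acta2 (19.4 ± 2.71 and 22.2 ± 2.80 FPKM) and Hopx (20.8 ± 2.93 and 22.6 ± 5.46 FPKM) were present in each library. Of the T, NKT and NK cell list, 3 genes were tested and 1 (Il7r) was lower, 2 adjusted over the list alone (camera adjusted p = 0.409), while Cd3e was listed at 0 and Trac did not exceed 0.2 FPKM in any library. Il7r did not pass without vehicle replicate 2 (adjusted p = 0.129), vehicle replicate 4 (0.103), sulfatide replicate 1 (0.0991) or sulfatide replicate 3 (0.0808). Only 2 genes each of the B cell list and of the eosinophil, basophil and mast cell list reached the level for testing, too few for a list test, and none passed. Of the lung epithelium list, 3 genes were tested and none passed, also adjusted over the list alone (camera adjusted p = 0.847), and Sftpc was listed at 0 in all 6 libraries. Of 9 endothelial and stromal genes 1 (Pdgfrb) was lower, also adjusted over the list alone (camera adjusted p = 0.262), and of 4 red cell and platelet genes none passed, also adjusted over the list alone (camera adjusted p = 0.803).

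Cell cycle genes were higher in sulfatide (15 of 42 members higher and none lower, 24 adjusted over the list alone, median 0.74, camera adjusted p = 1.25e-07, adjusted p = 0.733 with an estimated correlation and 0.185 by fry). The median was 0.302 with the replicate number as a block, where only replicates 2 and 3 set the difference. Kif20a rose 2.07-fold, Tk1 2.23-fold, Rrm2 3.07-fold and Birc5 2.33-fold. Mean log2 levels of the list were 4.18, 4.74 and 3.86 in vehicle replicates 2, 3 and 4, and 5.35, 4.96 and 4.53 in sulfatide replicates 1, 2 and 3, so that vehicle replicate 3 lay above sulfatide replicate 3. Tk1, Rrm2 and Birc5 did not pass without vehicle replicate 2 (adjusted p = 0.0753, 0.0653 and 0.0748) or without vehicle replicate 4 (0.0596, 0.0509 and 0.0527), nor Kif20a without vehicle replicate 2 (0.0555) or Birc5 without sulfatide replicate 1 (0.0523).

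Ribosomal protein and oxidative phosphorylation genes rose by small amounts. Of the 77 cytoplasmic ribosomal protein genes 32 rose and none fell, 56 adjusted over the list alone (median 0.31, camera adjusted p = 6.17e-14, adjusted p = 0.733 with an estimated correlation and 0.0701 by fry), with Rps29 up 1.39-fold and Rplp1 up 1.35-fold. Of the 68 oxidative phosphorylation genes 14 rose and 1 (Cycs) fell, 28 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 2.9e-08, adjusted p = 0.733 with an estimated correlation and 0.175 by fry), with Cox8a up 1.40-fold. The medians were 0.198 and 0.181 after rescaling to TPM and 0.204 and 0.148 with the replicate number as a block. Rescaling to TPM also lowered the median of all tested genes, from 0.0366 to -0.0627. Quantile normalization gave 0.186 for the ribosomal list. Rps29 and Rplp1 did not pass without vehicle replicate 2 (adjusted p = 0.0778 and 0.109), sulfatide replicate 1 (0.0505 and 0.085) or sulfatide replicate 3 (0.057 and 0.0698), nor Rplp1 without vehicle replicate 4 (0.083), and Cycs did not pass without vehicle replicate 2 (0.104), sulfatide replicate 2 (0.0514) or sulfatide replicate 3 (0.0832). Across genes, which are not independent replicates, the fold change fell with transcript length (Spearman's rho -0.29), and after removal of a trend on length and GC content the medians of these lists were 0.10 and 0.08, and Rps29, Rplp1 and Cox8a no longer passed (adjusted p = 0.21, 0.197 and 0.065). The 12 mitochondrially encoded mRNAs tested had a median of 0.14 (-0.0279 to 0.186 over the alternatives) and none passed, also adjusted over the list alone (camera adjusted p = 0.146, 0.0114 with the replicate number as a block, and 0.0479 without vehicle replicate 2 and 0.018 without sulfatide replicate 1).

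The hypoxia response list was higher (7 of 19 members higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.0088, adjusted p = 0.255 with an estimated correlation). Egln3 (1.85-fold) and Ddit4 (1.70-fold) rose while the growth factor Vegfa fell (1.40-fold). Ddit4 did not pass without vehicle replicate 2 (adjusted p = 0.0626). Cholesterol biosynthesis genes were higher (7 of 23 higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.00953, adjusted p = 0.733 with an estimated correlation, 0.0701 by fry, 0.0664 with array weights and 0.135 without sulfatide replicate 2), including Sqle (1.52-fold) and Fdps (1.37-fold). After rescaling to TPM the medians of the hypoxia and cholesterol lists were 0.201 and 0.112, and that of all tested genes was -0.0627 (0.0366 as designed). In the lung repair and fibrosis-associated macrophage list 8 of 19 members rose and 5 fell, also adjusted over the list alone (median 0.06, and -0.0459 to 0.159 over the alternatives, camera adjusted p = 0.471, 0.0311 by fry), with Timp1 and Fabp5 (2.32-fold) higher and Pdgfb (2.54-fold) lower.

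The remaining lists were not called. Of 28 genes for apoptotic cell uptake and phagocytosis, 4 rose and 4 fell, 6 and 5 adjusted over the list alone (camera adjusted p = 0.983), with the receptor Axl 3.48-fold lower and Scarb1 1.58-fold higher. Of 15 complement genes 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.975), with Cfb 1.90-fold lower and Cfp 1.68-fold higher. Of 10 MHC class II antigen presentation genes 1 (Ifi30) rose and 1 (H2-Ab1) fell, also adjusted over the list alone (camera adjusted p = 0.983). Of 34 lysosome genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.983). Of 21 glycolysis genes 1 (Aldoc) rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.596). Of 33 fatty acid oxidation and lipid storage genes 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.757), and of 30 NRF2 and oxidative stress genes 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.983). Of 26 unfolded protein response genes 3 rose and 3 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.983). Of 15 glucocorticoid response genes 4 rose, among them the metallothionein Mt1 (2.39-fold), and 3 fell, 5 each adjusted over the list alone (camera adjusted p = 0.998). Of 13 circadian clock genes 1 (Nfil3) rose, 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.998). Median, mean and test differed in sign for the CD1, apoptotic cell uptake, unfolded protein, clock and glucocorticoid lists. In all, 14 of 35 lists were called, 5 higher and 9 lower, of which none passed with an estimated correlation, while fry called 12 lists. Fry did not call the ribosomal protein, oxidative phosphorylation, cell cycle and cholesterol lists, and called the NKT cytokine and lung repair lists, which camera did not.

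**Figure D2:**
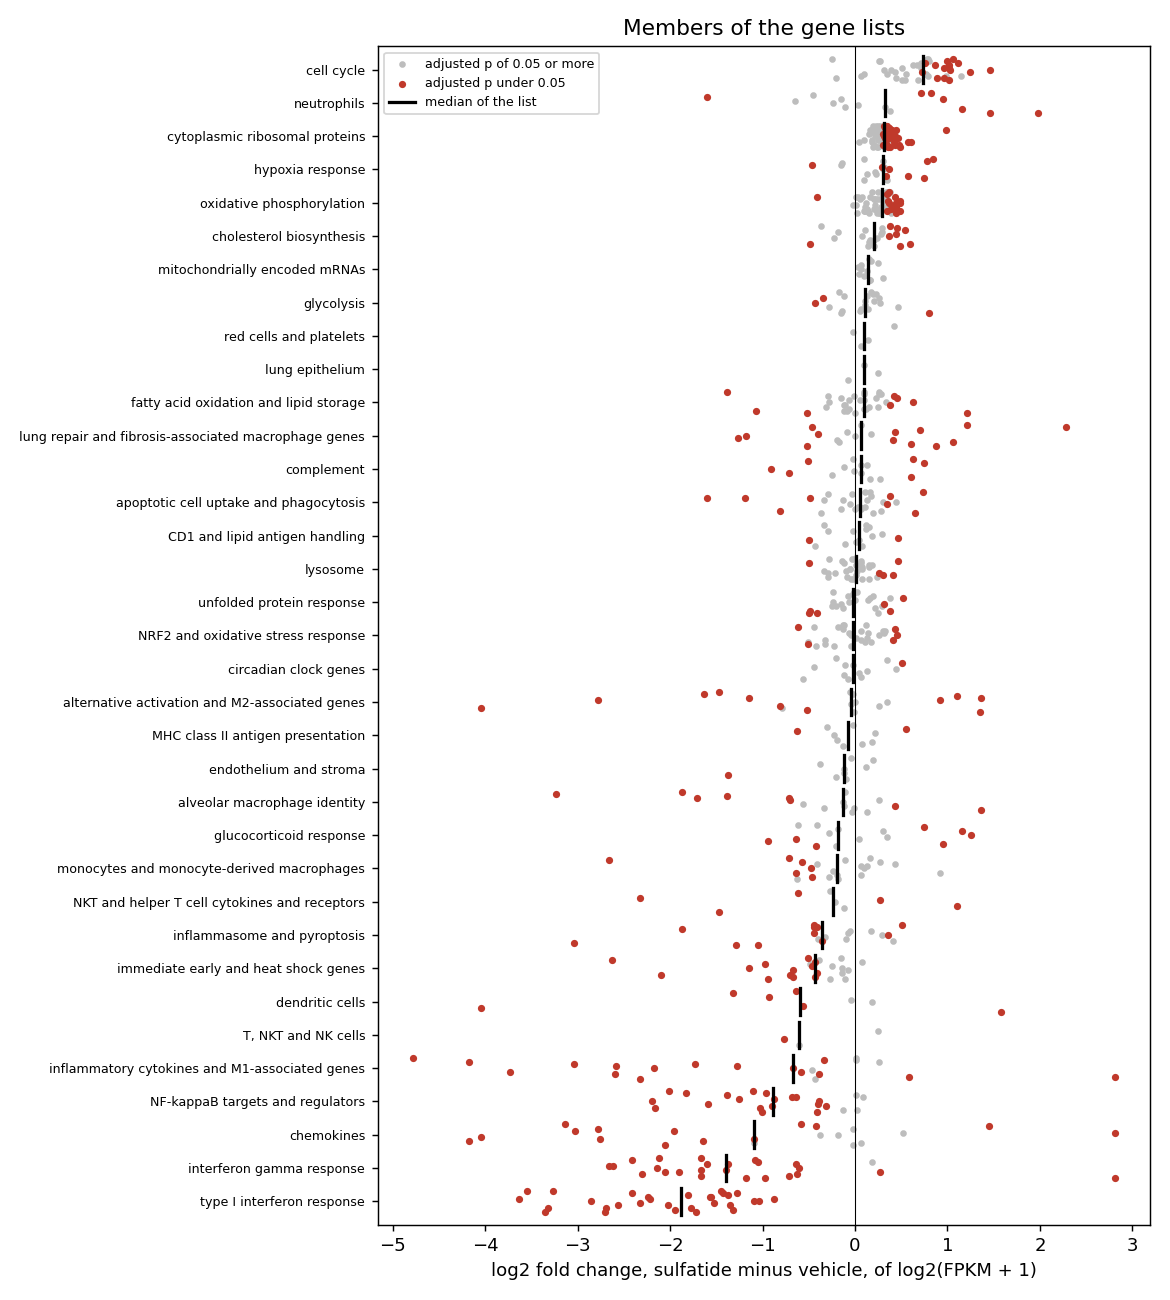
Log2 fold changes (sulfatide minus vehicle, log2(FPKM + 1)) of the tested members of 35 gene lists, with 1 point per gene, red where the adjusted p was below 0.05, and a black line at the median of each list. The type I interferon response list had the lowest median (-1.88) and the cell cycle list the highest (0.74).

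**Figure D3:**
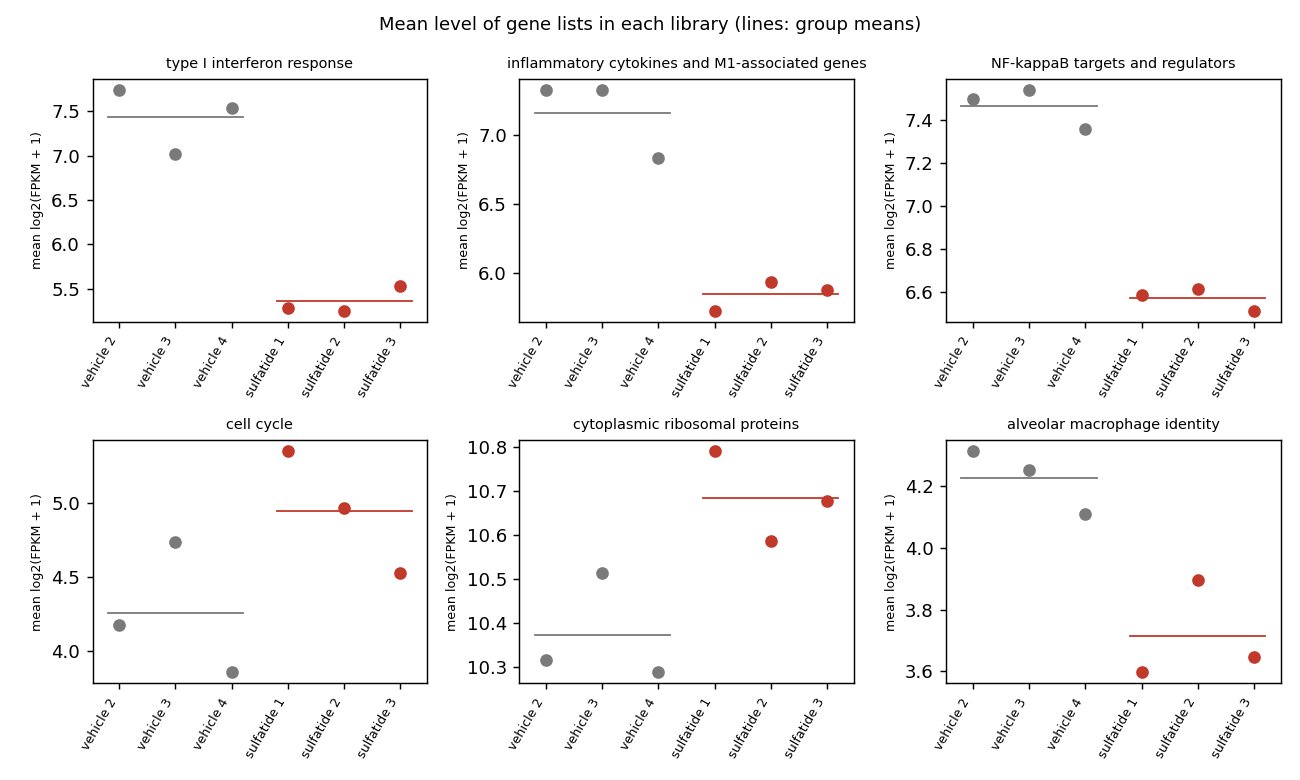
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each library (grey vehicle, red sulfatide), with a line at the mean of each group of 3 libraries. For the type I interferon response the vehicle libraries lay at 7.02 to 7.74 and the sulfatide libraries at 5.26 to 5.53, while for the cell cycle list vehicle replicate 3 (4.74) lay above sulfatide replicate 3 (4.53).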

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

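Leaving out Saa3 and removing the trend on length and GC content were chosen after the data were seen. None of the 1943 called genes had the opposite sign under any alternative that tested it. In 1912 of them the groups did not overlap, so leaving out a library could not reverse the sign. The counts of genes higher and lower (865 and 1078 as designed) stayed within 1.5 times of these under both other pseudocounts, the filter at 5 FPKM, median-of-ratios scaling, quantile normalization, robust eBayes, eBayes without a trend and both added alternatives. The number of higher genes was 522 with no filter, 468 after rescaling to TPM and 2054 with array weights, which also gave 1723 lower genes. FPKM sums were higher in each sulfatide library than in any vehicle library. Rescaling to TPM therefore moved the median log2 fold change of the genes tested from 0.0366 to -0.0627. Without 1 library, higher genes ranged from 268 (without vehicle replicate 2) to 1421 (without vehicle replicate 3), with 432 without vehicle replicate 4, 354 without sulfatide replicate 1 and 450 without sulfatide replicate 3, and lower genes from 642 (without vehicle replicate 2) to 1135 (without sulfatide replicate 2), with 682 without sulfatide replicate 3. Fewer libraries leave less power, and apart from the rescaling to TPM the cause of the other shifts was not tested. The number of lists called was 12 to 15 under these alternatives, 13 to 16 without 1 library, 12 by fry and 0 with an estimated correlation. None of the 14 called lists and 117 called named genes had the opposite sign under any alternative that tested them, whereas 15 of the 21 lists and 13 of the 33 named genes that were not called did under at least 1. Calls favour large changes, so this contrast is in part set by the calling itself. Of 150 named genes, 27 lost their call with the replicate number as a block, 28 without vehicle replicate 2, 17 without vehicle replicate 4 and 18 each without sulfatide replicates 1 and 3.

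With the replicate number as a block, 297 genes were higher, 635 lower and 16 lists called, and 882 of the 1943 genes kept their call. The groups shared only the numbers 2 and 3. Deviations from the group means correlated at 0.16 for the libraries numbered 2 and -0.30 for those numbered 3, so the numbers are not shown to pair the libraries. The highest such correlation, 0.54, was between vehicle replicate 3 and sulfatide replicate 1. These libraries also had the highest mean log2 level of the cell cycle list in their groups (4.74 and 5.35). What they share was not tested.

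The absolute depth is unknown, so no floor can be given for genes listed at 0. The groups were of equal size (n = 3), and 3517 genes had an unadjusted p below 0.05.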

Other observations

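The groups of related gene symbols described first, the tests for Saa3, monocytes, dendritic cells or lymphocytes and neutrophils, and the trend fitted without the list members were chosen after the results were seen. The symbol families were formed from gene names, and the genes in them were named after their values were seen. Of 339 families with at least 5 tested genes, 11 held more lower genes than independent draws of genes would give (hypergeometric test, Benjamini-Hochberg adjusted). Another 2, the ribosomal Rpl and Rps, held more higher genes. Genes of a family can move together, so these p-values are too small and do not measure the spread between libraries. Families that no list held were the schlafens, of which 7 of 7 fell (adjusted p = 2.14e-05, median log2 fold change -1.55), and the ADP-ribosyltransferases named Parp, of which 7 of 12 fell (adjusted p = 0.00422, median -0.67). Slfn1 fell from 85.9 ± 37.5 to 9.85 ± 2.91 FPKM and Parp14 from 72.5 ± 10.7 to 24.7 ± 2.27 FPKM (n = 3 each). The Ifi family, DNA sensors of the Ifi200 cluster among them, had 14 of 16 members lower (adjusted p = 1.01e-09) and the Trim family 16 of 37 (adjusted p = 3.35e-05). Members of these families share sequence, so values of single members are uncertain.

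The interferon ligand Ifnb1 was at 0.283 ± 0.140 FPKM in vehicle and 0.287 ± 0.147 in sulfatide, below the level for testing. The cytokines Il15 (113 ± 23.7 to 18.2 ± 3.17 FPKM) and Il27 (29.8 ± 5.21 to 8.12 ± 1.13 FPKM) and the activation marker Cd69 (44.1 ± 7.75 to 7.38 ± 1.17 FPKM) fell, while the interleukin-1 receptor antagonist Il1rn (689 ± 178 to 1285 ± 185 FPKM) and Spp1 (1496 ± 328 to 2729 ± 434 FPKM) rose.

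For the lower interferon and cytokine genes, 96 list members called lower had a median log2 fold change of -1.67. They came from more lists than the interferon response, inflammatory cytokine and chemokine lists. They were chosen because they were called lower, so a strongly negative median was set by their choice. The rise of the Saa3 share would lower every other gene by a log2 fold change of at most -0.0686, and the median was -1.63 after the trend on length and GC content was removed (95% bootstrap interval over genes -2.03 to -1.40), which argues against both as the cause. The 10 markers tested of dendritic cells and lymphocytes (Flt3, Zbtb46, Xcr1, Clec9a, Cd3d, Cd3e, Cd3g, Trac, Ncr1 and Cd79a) reached at most 0.240 FPKM in any vehicle library, against a median of 206 FPKM for the called members. They were chosen after the results were seen. Other members of the cell lists had higher means in vehicle, such as Cd247 (7.46 FPKM) and Il7r (4.34 FPKM). The dendritic cell list was itself called lower, so these markers do not decide whether such cells were lost. The monocyte list had a median of -0.19 (95% bootstrap interval -0.47 to 0.07, and -0.337 without vehicle replicate 3, -0.0993 without vehicle replicate 2, -0.117 without vehicle replicate 4 and -0.0206 with the replicate number as a block), but macrophages express most of its genes, so a smaller share of monocytes cannot be told apart from a lower level per cell. A lower level per cell in sulfatide-treated mice remains a hypothesis that these data may allow, and other differences between the groups were not tested.

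The small rise of ribosomal protein and oxidative phosphorylation genes went with transcript length. Removing the trend from each library lowered the medians from 0.31 to 0.10 and from 0.29 to 0.0777, a test fixed before its result was seen, with a bound of 0.1. A trend fitted without the members of these lists left 0.0772 and 0.0569. Rescaling to TPM alone left 0.198 and 0.181, but it also lowered the median of all tested genes from 0.0366 to -0.0627. Both lists were still called by camera after the trend was removed (adjusted p = 0.00039 and 0.0332), though before its removal neither passed with an estimated correlation (adjusted p = 0.733), so a length trend may account for much of the rise and the rest stays open. What produces the trend was not tested.

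For genes that rose, neutrophils are a candidate source of S100a8 and Lcn2, which were at 361 FPKM or more in each sulfatide library. S100a9, which neutrophils hold at about the level of S100a8, and Retnlg, Cxcr2 and Ly6g reached at most 35.2 FPKM there, which argues against neutrophils for these genes. Liver RNA is a candidate source of Ambp, Hp and Saa1, but the liver genes Alb and Apoa1 were listed at 0 FPKM in each sulfatide library, where Ambp was at 16.8 FPKM or more. Which cells expressed these genes stays open.

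The 6 libraries can be divided into 2 groups of 3 in 10 ways, too few for a share below 0.05. The real division gave 1943 called genes, as many as in 1 of the 10 divisions, and the highest of the others was 0. For gene lists the real division gave 14 by camera, and as many or more were called in 4 of the 10. The other divisions gave 5 to 16 lists by camera, although no gene was called in them. By fry the real division gave 12 lists and the highest of the others 0. The other divisions mix the groups, so that the difference between the groups enters their spread. A large difference therefore holds down their calls of single genes and of lists by fry. Part of it also remains in the comparison that each of them makes, so the lists camera called in them are not a rate of false calls.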
